A study of Arabidopsis thaliana with 6 samples.

How the data were processed

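RNA-seq libraries from Arabidopsis thaliana siliques, the fruits that hold the developing seeds, were compared between WT and the mutant agc1-4. All 6 libraries were taken 3 days after pollination, 3 per genotype. Per the labels, siliques were frozen, RNA was extracted with Trizol and Illumina libraries were made by a standard protocol. The labels did not say whether the 3 libraries of a genotype came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

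The authors deposited 1 table of 27779 gene rows with 12 value columns, 2 for each library. Of these, 6 columns held estimated counts, per the file headers and the values deposited, of which between 4.32% and 4.86% per library were not whole. The other 6 columns held FPKM (fragments scaled to gene length and library size), per the file headers, as computed by the authors. The aligner, the counting tool, the genome build and the strand of the libraries were not given in the sources used here. Estimated counts that are not whole can arise where reads are divided between features, so values of near-identical copies are uncertain. This applies to CAB1, to the RBCS genes, to the SAUR19 to SAUR24 cluster, to AT5G38160 and AT5G38180, to VGD1 and VGDH1, to core histones and to overlapping or antisense genes. Of the rows, 27420 had a locus that also stands in the RefSeq annotation of Arabidopsis (assembly TAIR10.1), which served only for gene names, for which genes neighbour each other and for GC content and transcript length. No coordinates are given, because the build behind the deposited values was not named. Another 151 rows carried XLOC names for gene models outside named loci.

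Estimated counts were rounded to whole numbers. Differences were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr and the robust quasi-likelihood F-test without covariates. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are agc1-4 over WT, and the SE of a log2 fold change is its size divided by the square root of F. The filter removed 8951 rows, 3953 of which were 0 in every library, and left 18828. Levels are given as mean FPKM ± SD over 3 libraries. The target gene was also tested with an exact two-sided permutation test, which cannot give a p below 0.1 with 3 libraries against 3. Neither the table nor the reference names a locus AGC1-4; the gene was taken as AT5G40030 from background knowledge.

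Before the data were examined, 25 gene lists with 402 members were fixed by locus. For 400 members the symbol matched a name in the table or reference, the other 2 (AGL40 and HSP22) were not contradicted, and 0 were dropped. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the 24 lists that had tested members. GO terms of the table were tested one-sided with the hypergeometric distribution, separately for higher and lower genes, over 66 terms with 10 to 500 of the 18059 tested genes that had a term. Named genes followed a rule of 4 parts. It took AGC1-4, then the 10 called genes with the largest fold in each direction with a mean FPKM of at least 1 and no overlap of FPKM values between genotypes. It also took up to 4 called members of each list by adjusted p (in a list without calls, up to 2 members by p), and up to 4 called members of the 2 leading GO terms per direction. The rule gave 103 genes besides AGC1-4, and not all are named in the text.

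Total counts per library ranged from 7973366 to 11812934. A count of 0 in a library allows up to 3 counts, which is 0.254 to 0.376 CPM, and covers counting error only. In simulated counts for 18694 genes of the agc1-4 against WT comparison, edgeR recovered 46 of 67 genes changed 1.5-fold, 60 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 15 false calls among 194. The other 8 calls were genes of the shifted list described next. Camera called a simulated list of 20 genes shifted by 0.4 on the log2 scale and 0 of 24 unshifted lists. Genes were simulated independently of each other, while estimated correlations in the real lists reached 0.614 (pollen markers). The simulation therefore cannot show how often lists of correlated genes are called falsely. It also changed few genes and gave 194 calls, where the real data gave 2564. The adjusted p of a gene depends on how many others change, so these recovery rates need not hold in the real data.

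The alternatives were RLE size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, limma on log2(FPKM + 1) and on log2(FPKM + 0.1) over genes with an FPKM of at least 1 in at least 3 libraries, the replicate number as a block, each library left out in turn, stricter thresholds, an estimated inter-gene correlation, and fry. Median-ratio and quantile scaling of FPKM had been planned only for a table without counts and were not used. Chosen after seeing the data were scaling by library size alone, removal of each library's trend with GC content and transcript length, leaving out XLOC and organellar genes, KEGG pathways, and 6 gene families picked by words of the table's descriptions. Adjusted p-values of the families are over these 6 unless given as over the 30 lists and families. No column was left without a sample.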

Results

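Transcript levels were measured by RNA-seq in siliques of Arabidopsis thaliana 3 days after pollination, in 3 WT libraries and 3 libraries of the agc1-4 mutant. Total counts were 8460230, 11663034 and 8429300 in WT replicates 1, 2 and 3, and 11812934, 9588011 and 7973366 in agc1-4 replicates 1, 2 and 3. Between 21813 and 22295 genes had a count in each library. The Pearson correlation of log2 CPM (counts scaled to library size) across genes, which are not independent replicates, was 0.987 to 0.991 within a genotype and 0.975 to 0.980 between genotypes. The leading principal component held 49.0% of the variance and separated the genotypes. The next held 14.66% and set WT replicate 3 apart, at -25.27 against -4.08 to 12.88 for the other libraries. The comparison asked which transcripts differ between WT and agc1-4 siliques.

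AGC1-4, taken as the protein kinase gene AT5G40030, was lower in every agc1-4 library than in every WT library. Its FPKM was 0.63, 1.78 and 1.01 in WT replicates 1 to 3 (mean 1.14 ± 0.586, SD, n = 3) and 0.09, 0.39 and 0.07 in agc1-4 replicates 1 to 3 (mean 0.183 ± 0.179). The log2 fold change was -2.66 ± 0.54 (SE), with an adjusted p of 0.000983 in edgeR. An exact two-sided permutation test on FPKM gave p = 0.1, the smallest it can give. The gene was weakly expressed, with 10, 39 and 16 counts in WT and 2, 7 and 1 in agc1-4. Without agc1-4 replicate 2 the log2 fold change was -3.76, and without WT replicate 2 the gene did not pass the filter on low counts and was not tested.

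In agc1-4 siliques, LEC1, LEC2 and WOX8, transcription factor genes of the early embryo, were higher than in WT. The embryo list as a whole was not called (camera adjusted p = 0.208), and 2 of its members were lower. The heat shock and endosperm lists were called higher with a fixed inter-gene correlation, but not with an estimated one (adjusted p = 0.0568 and 0.103). Likewise, genes of wall loosening, photosynthesis, auxin transport, touch response and salicylic acid defence were called lower with the fixed correlation, but not with an estimated one (adjusted p = 0.0512, 0.29, 0.103, 0.103 and 0.188). The alternative list test fry called the heat shock and endosperm lists and each of these (fry adjusted p = 0.000605 to 0.029). Fry asks whether the members of a list change at all, while camera asks whether they change more than other genes. With 13.6% of tested genes called, a fry call does not show that a list stands out. Changes were mostly small: the median size among called genes was 0.404 on the log2 scale. Of 18828 genes tested, 2564 (13.6%) were called by edgeR, 1233 higher and 1331 lower in agc1-4. A fold of at least 2 was seen for 305 called genes, 224 higher and 81 lower. FPKM values of the genotypes did not overlap for 29.5% of tested genes, where chance gives 10%. The DESeq2 Wald test called 1590 genes, and 1688 were called without agc1-4 replicate 2, of which 1534 and 1608 were also called with all libraries in edgeR.

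Among called genes, the transcript with the deepest loss was DIR1 (AT5G48485), which encodes a lipid-transfer protein of systemic acquired resistance. It had 653 counts over the WT libraries (27.3 ± 7.57 FPKM, SD, n = 3) and 0 in agc1-4, at least 224-fold lower against a floor of 3 counts over the group (adjusted p = 1.52e-06). AT5G59050, a gene of unknown function, fell from 44.4 ± 1.18 to 9.34 ± 0.692 FPKM, a log2 fold change of -2.26 ± 0.08 (SE, adjusted p = 3.29e-17). WRKY40, a stress-induced transcription factor gene, fell 4.85-fold (adjusted p = 0.000109) and IAA6, an auxin-induced repressor of auxin responses, fell 3.00-fold (adjusted p = 0.000251). The nitrate transporter gene NRT2.5 fell 2.82-fold (adjusted p = 0.00155) and AT1G62500 fell 3.25-fold (adjusted p = 0.000276). Also lower were AT1G65486, the peptide precursor gene CEP13, DRMH1 and AT5G53820, by 4.41-fold, 3.26-fold, 3.03-fold and 2.90-fold. CEP13 and DRMH1 lost their calls without agc1-4 replicate 2 (adjusted p = 0.0581 and 0.0516), AT5G53820 without WT replicate 1 (adjusted p = 0.0559) or agc1-4 replicate 1 (adjusted p = 0.0775), and AT1G65486, 6.87-fold lower without agc1-4 replicate 1, in limma with a pseudocount of 0.1 (adjusted p = 0.225).

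Among the genes that rose, the small heat shock protein gene HSP22 had 0 counts in WT and 63 in agc1-4, at least 20.4-fold higher against the same floor (adjusted p = 3.44e-06). AT1G71250, which encodes a GDSL esterase or lipase, rose 50.7-fold from 0.113 ± 0.0586 to 5.95 ± 1.29 FPKM (SD, n = 3; adjusted p = 6.49e-11). AT1G75945 rose from 1.08 ± 0.406 to 35.6 ± 1.52 FPKM, a log2 fold change of 5.03 ± 0.25 (SE, adjusted p = 1.74e-14). The lipid-transfer family gene AT5G38160 rose from 1.19 ± 0.138 to 37.3 ± 2.89 FPKM (adjusted p = 1.74e-14), and its near neighbour AT5G38180 rose 19.0-fold (adjusted p = 6.02e-10). Reads may be divided between close relatives in that cluster, so the values of single members are uncertain. The pectinesterase gene PME6 rose 22.5-fold (adjusted p = 3.14e-09) and AT3G12880, described as a pectin methylesterase inhibitor, 19.2-fold (adjusted p = 5.76e-07). A gene described as a Copia-like retrotransposon, AT1G21280, rose 18.4-fold, the transcription factor gene GATA29 10.5-fold and AT5G63250 9.85-fold (adjusted p = 2.64e-06, 2.95e-07 and 3.91e-08). With few WT counts, the fold of AT3G12880 was 49.1 without WT replicate 2, and that of AT1G21280 was 55.6 without WT replicate 1 and 11.2 without WT replicate 2.

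**Figure D1:**
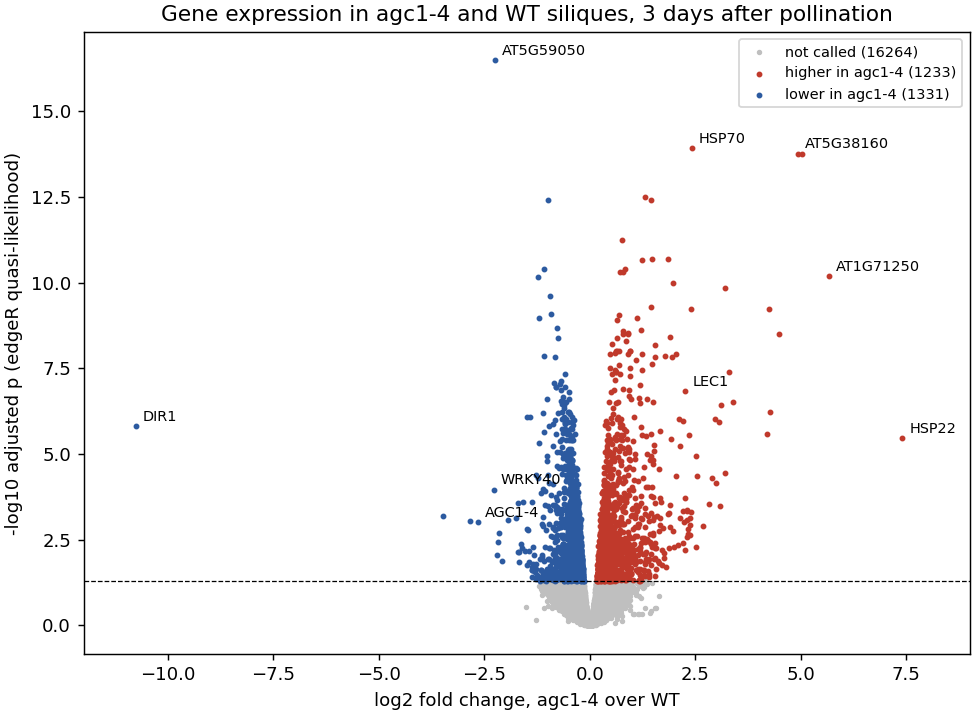
Each point is 1 of the 18828 tested genes, with the log2 fold change (agc1-4 over WT) on the x axis and -log10 of the adjusted p from edgeR on the y axis; the dashed line marks an adjusted p of 0.05. Red points are the 1233 genes called higher and blue points the 1331 called lower in agc1-4; DIR1 and HSP22, with 0 counts in 1 genotype, lie at fitted values that depend on the prior count.

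Endosperm genes were higher in agc1-4. Of 19 tested members, 5 rose and 0 fell (6 and 0 adjusted over the list alone), with a median log2 fold change of 0.35 (camera adjusted p = 0.00226; adjusted p = 0.103 with an estimated correlation). The median was 0.15 without WT replicate 3, 0.21 without agc1-4 replicate 1 and 0.24 after removal of GC and length trends. MPC, a maternally expressed imprinted gene, rose from 61.1 ± 4.11 to 95.0 ± 9.08 FPKM (log2 fold change 0.63 ± 0.08, adjusted p = 3.82e-06). FWA, also imprinted, rose 1.31-fold and the MADS-box gene AGL40 1.46-fold (adjusted p = 0.000223 and 0.00038). ZOU, a regulator of endosperm breakdown, rose from 1.45 ± 0.122 to 3.47 ± 0.565 FPKM (log2 fold change 1.24 ± 0.28, adjusted p = 0.00277).

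Embryo genes went both ways: 3 of 12 tested members rose and 2 fell, the same counts when adjusted over the list alone. The list was not called (median log2 fold change 0.00, from -0.10 to 0.17 over the alternatives, mean 0.49, camera adjusted p = 0.208). LEC1 rose from 2.11 ± 0.908 to 9.69 ± 0.701 FPKM (log2 fold change 2.26 ± 0.25, adjusted p = 1.45e-07). LEC2, with 3 to 5 counts per WT library, rose 3.96-fold and WOX8 2.47-fold (adjusted p = 0.00526 and 0.00838); WOX8 was not called by DESeq2 (adjusted p = 0.0566). STM, a shoot meristem gene, was 1.39-fold lower (adjusted p = 0.0177), but 0 members fell without WT replicate 1, without agc1-4 replicate 1, without agc1-4 replicate 2, in DESeq2 or in limma, and 1 fell without agc1-4 replicate 3 or after removal of GC and length trends. No gene of the seed storage list, whose transcripts accumulate later in seed filling, had enough counts to be tested; the highest value in any library was 11 counts. Without the filter on low counts 5 were fitted and 1 was called higher (median log2 fold change 2.23), while DESeq2 called 0 of 5 (median 2.44).

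Seed coat flavonoid genes were not called as a list (median log2 fold change 0.06, camera adjusted p = 0.283), with 3 of 18 tested members higher and 0 lower (4 and 1 adjusted over the list alone). TT8, a regulator of tannin synthesis, rose 1.21-fold (adjusted p = 0.00262), as did TT10 and MYB5 by 1.38-fold and 1.19-fold (adjusted p = 0.0189 and 0.0368). TT10 lost its call in DESeq2 and without WT replicate 2, agc1-4 replicate 1 or agc1-4 replicate 2 (adjusted p = 0.0539 to 0.0995), and MYB5 in most alternatives (adjusted p = 0.0649 to 0.201). Only 1 member rose without agc1-4 replicate 1, without agc1-4 replicate 2 or in DESeq2. The list itself was called without WT replicate 3 (median 0.14, adjusted p = 0.0313), while without WT replicate 2 its median was 0.00 and 1 member fell. Of 15 seed size genes, CKX2, a cytokinin-degrading enzyme gene active in endosperm, rose from 41.8 ± 2.83 to 67.9 ± 1.58 FPKM (log2 fold change 0.70 ± 0.07, adjusted p = 1.01e-08). CYP78A5, a maternal promoter of seed growth, fell 1.91-fold (adjusted p = 0.000414), and ARF2 was the other of 2 that fell, with 1.12-fold (adjusted p = 0.0265). The ARF2 call was lost without WT replicate 1 or any 1 of the agc1-4 replicates, in limma, and after removal of GC and length trends, where its log2 fold change was -0.09 (adjusted p = 0.0786 to 0.252). The counts over the list alone were the same, and the list was not called (median -0.05, and -0.10 without agc1-4 replicate 3; camera adjusted p = 0.874). Of 33 cell cycle genes, 4 rose and 0 fell, also over the list alone, among them the replication genes MCM6 and PCNA2 by 1.35-fold and 1.30-fold (adjusted p = 0.00322 and 0.00541). That list was not called by camera either (median 0.09, camera adjusted p = 0.235) but was by fry (fry adjusted p = 0.029). Only 2 members rose without WT replicate 1, without agc1-4 replicate 2, without agc1-4 replicate 3 or in DESeq2.

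**Figure D2:**
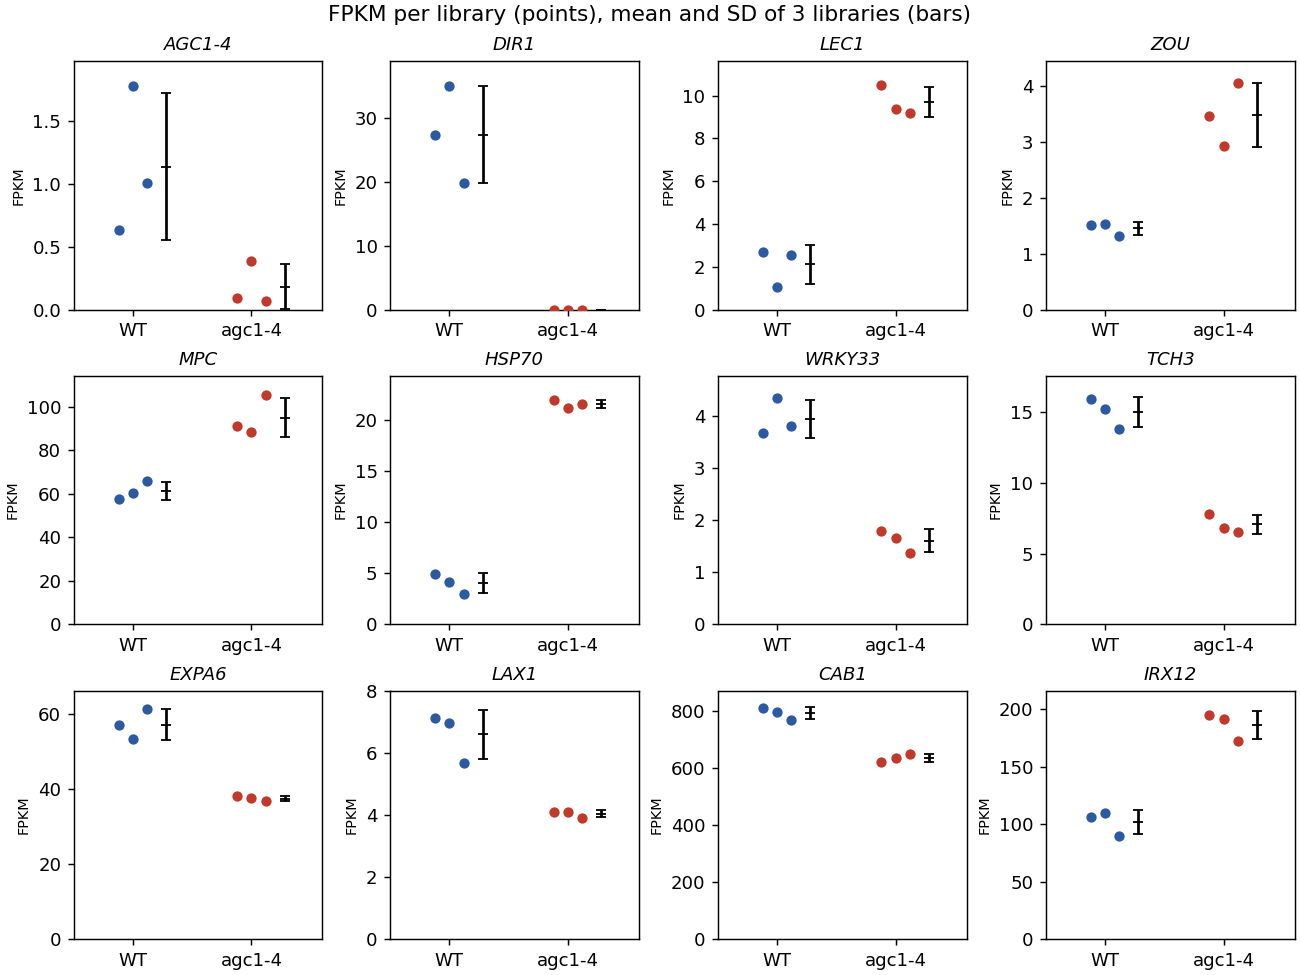
FPKM (y axis, starting at 0) of 12 genes in WT and agc1-4 siliques; points are the 3 libraries of a genotype, and the bar beside them is their mean and SD. The genotypes do not overlap in any panel; DIR1 is at 0 in the 3 agc1-4 libraries and LEC1 rises from a mean of 2.11 to 9.69.

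Expansin genes, whose products loosen cell walls during growth, were lower in agc1-4. Of 15 tested cell expansion genes, 10 fell and 0 rose, also over the list alone, with a median log2 fold change of -0.39 (camera adjusted p = 4.96e-10; adjusted p = 0.0512 with an estimated correlation). EXPA6 fell from 57.3 ± 4.04 to 37.5 ± 0.699 FPKM (log2 fold change -0.61 ± 0.07, adjusted p = 3.69e-07). EXPA5 and XTH4 fell by 1.49-fold and 1.43-fold, and EXPA8 by a log2 fold change of -0.59 ± 0.08 (adjusted p = 1.16e-06, 2.51e-06 and 9.6e-06). Of the 6 xyloglucan endotransglucosylase genes in the list only XTH4 and XTH9 fell, and XTH33 had a log2 fold change of 0.49 ± 0.32 (adjusted p = 0.346).

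Auxin transport genes were lower as a group. Of 13 tested members 6 fell and 0 rose, also over the list alone (median log2 fold change -0.20, camera adjusted p = 0.0021; adjusted p = 0.103 with an estimated correlation). The auxin influx carrier gene LAX1 fell from 6.60 ± 0.789 to 4.04 ± 0.118 FPKM (log2 fold change -0.77 ± 0.15, adjusted p = 0.000524), and AUX1 fell 1.34-fold (adjusted p = 0.000719). Only 3 members fell without WT replicate 1, without agc1-4 replicate 2 or after removal of GC and length trends, and 2 fell in limma. Of 28 auxin response genes, 4 fell and 0 rose (9 and 0 adjusted over the list alone; median -0.13, camera adjusted p = 0.0106; adjusted p = 0.346 with an estimated correlation). Besides IAA6 these were IAA7, GH3.5 and GH3.6, at 1.16-fold, 1.25-fold and 1.39-fold lower (adjusted p = 0.00488, 0.0182 and 0.0272). GH3.5 and GH3.6 lost their calls in DESeq2, in limma and without WT replicate 1 or agc1-4 replicate 2 among others (adjusted p = 0.0673 to 0.142), and IAA7 without agc1-4 replicate 2 (adjusted p = 0.0596). The number that fell was 2 without WT replicate 1 and in DESeq2, 1 without agc1-4 replicate 2 and 11 after removal of GC and length trends, and the list was not called without WT replicate 1 (adjusted p = 0.0583). None of 5 tested auxin synthesis genes was called, also over the list alone (median 0.20, camera adjusted p = 0.193), though fry called the list (fry adjusted p = 0.00467). Over the 11 members measured without the filter on low counts the median turned to -0.19, and to -0.25 in DESeq2. YUC6 had a log2 fold change of 0.20 ± 0.08 (adjusted p = 0.102, but 0.0126 without WT replicate 2 and 0.0446 after removal of GC and length trends) and TAA1 of 0.83 ± 0.36 (adjusted p = 0.128).

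Relatives of AGC1-4 in the AGC kinase family were lower in part: 3 of 12 tested members fell and 0 rose (4 and 0 adjusted over the list alone; median log2 fold change -0.16, camera adjusted p = 0.0195; adjusted p = 0.346 with an estimated correlation). PHOT2, a blue light receptor kinase, fell from 47.6 ± 2.86 to 37.1 ± 1.57 FPKM (log2 fold change -0.30 ± 0.06, adjusted p = 0.00047). WAG1 and PID, kinases that act on auxin efflux carriers, were 1.75-fold and 1.31-fold lower (adjusted p = 0.0148 and 0.0329). WAG1 lost its call in DESeq2 and without WT replicate 1 or 3 or agc1-4 replicate 1 or 2 (adjusted p = 0.0594 to 0.0931), and PID in DESeq2, in limma and without WT replicate 1 or 2 or agc1-4 replicate 1 or 2 (adjusted p = 0.0589 to 0.244). The list lost its call without WT replicate 1, where its median was -0.10, without agc1-4 replicate 1 and after removal of GC and length trends (adjusted p = 0.11, 0.0853 and 0.0814).

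Lists for cytokinin, gibberellin and brassinosteroid were not called in edgeR with camera, though the gibberellin list was called lower in limma on log2(FPKM + 1) (adjusted p = 0.048). The cytokinin list was called by fry (fry adjusted p = 0.032). CKX2 was the only 1 of 10 cytokinin genes that rose, and 0 fell (2 and 0 adjusted over the list alone; median log2 fold change 0.12, camera adjusted p = 0.166). The cytokinin median was 0.05 without WT replicate 1 and turned to -0.05 and -0.04 over 14 members without the filter on low counts and in DESeq2; 2 members rose without WT replicate 3 and in limma. Of 12 gibberellin genes, GA2OX2, which inactivates gibberellin, fell 1.43-fold (adjusted p = 0.00145) and GASA4 was 1.54-fold lower (adjusted p = 0.0183). Adjusted over the list alone, 1 was higher and 2 were lower (median -0.12, camera adjusted p = 0.233), and the GASA4 call was lost in DESeq2, in limma, without WT replicate 1 or 3 and without agc1-4 replicate 1 or 3 (adjusted p = 0.0559 to 0.132). Of 10 brassinosteroid genes the receptor gene BRI1 and BES1 were called lower and DET2 higher, also over the list alone (adjusted p = 0.00471, 0.0411 and 0.0446; median -0.13, camera adjusted p = 0.193). The DET2 call was lost in each of the 6 fits without 1 library (adjusted p = 0.0506 to 0.138) and in DESeq2 (adjusted p = 0.185). The BES1 call was lost in DESeq2, in limma and without WT replicate 2, agc1-4 replicate 1 or agc1-4 replicate 3 (adjusted p = 0.135 to 0.2). Without agc1-4 replicate 1, and after removal of GC and length trends, 0 of the 10 were called.

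Photosynthesis genes of the nucleus were lower in agc1-4 by a small amount. Of 23 tested members, 15 fell and 0 rose (18 and 0 adjusted over the list alone), with a median log2 fold change of -0.19 (camera adjusted p = 2.23e-09; adjusted p = 0.29 with an estimated correlation). The light-harvesting gene CAB1 fell from 791 ± 20.6 to 635 ± 14.5 FPKM (log2 fold change -0.32 ± 0.05, adjusted p = 2.49e-05). GAPB, an enzyme gene of carbon fixation, fell 1.22-fold (adjusted p = 0.000252), and the Rubisco small subunit genes RBCS2B and RBCS3B fell 1.22-fold and 1.19-fold (adjusted p = 7.22e-05 and 0.000268). CAB1 and the RBCS genes have near-identical copies, so the split of reads among copies is uncertain. Genes encoded by the chloroplast held 0.0133% to 0.0276% of counts in WT and 0.0177% to 0.0698% in agc1-4, with the highest share in agc1-4 replicate 3. Of 31 tested chloroplast genes, 0 were called higher and 1 was called lower. Mitochondrially encoded genes held 0.00167% to 0.00272% in WT and 0.00306% to 0.00627% in agc1-4, and 4 of 10 tested were called higher.

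Heat shock genes were higher in agc1-4, with 4 of 6 tested members risen and 0 fallen, also over the list alone (median log2 fold change 1.01, the same with HSP22 at its bound; camera adjusted p = 1.33e-15; adjusted p = 0.0568 with an estimated correlation). The chaperone gene HSP70 (AT3G12580) rose from 4.05 ± 0.986 to 21.6 ± 0.425 FPKM (log2 fold change 2.41 ± 0.11, adjusted p = 1.19e-14), and HSP90.1 rose 3.15-fold (adjusted p = 2.06e-06). HSP101 was 1.28-fold higher (adjusted p = 0.0127), with its call lost in DESeq2, in limma and without WT replicate 3 or agc1-4 replicate 3 (adjusted p = 0.0529 to 0.101). Over 11 members without the filter on low counts the median was 1.66.

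Genes of touch and handling were lower. Of 8 tested members 6 fell and 0 rose (7 and 0 adjusted over the list alone), with a median log2 fold change of -0.97 (camera adjusted p = 4.23e-08; adjusted p = 0.103 with an estimated correlation). In limma on log2(FPKM + 1) the median was -0.63. The calmodulin-like gene TCH3 fell from 15.0 ± 1.08 to 7.07 ± 0.658 FPKM (log2 fold change -1.11 ± 0.13, adjusted p = 6.15e-07). WRKY33, a defence regulator gene, fell 2.44-fold and TCH4, a wall enzyme gene, had a log2 fold change of -0.58 ± 0.12 (adjusted p = 4.15e-05 and 0.00131). Salicylic acid defence genes were lower too, with 3 of 10 tested members fallen and 0 risen (6 and 0 adjusted over the list alone; median -0.50, camera adjusted p = 0.00066; adjusted p = 0.188 with an estimated correlation). WRKY54, WRKY70 and EDS1 fell by 1.84-fold, 1.62-fold and 1.63-fold (adjusted p = 0.000311, 0.000719 and 0.00132).

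Of 14 ABA and drought genes, 4 fell and 1 rose (5 and 1 adjusted over the list alone; median log2 fold change -0.18, camera adjusted p = 0.0315; adjusted p = 0.306 with an estimated correlation). The dehydrin genes COR47 and ERD10 fell 1.54-fold and 1.37-fold and RD29A fell 1.36-fold (adjusted p = 8.43e-07, 5.56e-05 and 0.000592), while HAI1, a phosphatase gene that damps ABA signalling, rose 1.64-fold (adjusted p = 1.63e-06). The list lost its call without WT replicate 1 (adjusted p = 0.0991), without agc1-4 replicate 3 (adjusted p = 0.0969) and in limma with either pseudocount (adjusted p = 0.0916 and 0.0949), and its median was -0.28 without agc1-4 replicate 1. Jasmonate genes were not called as a list (median -0.02, mean -0.01, camera adjusted p = 0.538 in the upward direction), with 2 of 13 higher and 1 (JAZ9) lower, also over the list alone; 0 were lower in DESeq2, in limma and without WT replicate 1 or 3 or agc1-4 replicate 1 or 2. VSP2, a storage protein gene, rose from 109 ± 5.08 to 175 ± 4.28 FPKM (log2 fold change 0.68 ± 0.06, adjusted p = 8.47e-10) and LOX3 rose 1.24-fold (adjusted p = 0.00524). None of 6 morning and 8 evening clock genes was called, also over each list alone (medians -0.02 and -0.05, from -0.07 to 0.02 and from -0.09 to -0.01 over the alternatives; camera adjusted p = 0.874 and 0.781). The leading members were PRR7 with a log2 fold change of -0.12 ± 0.06 and ELF3 with -0.09 ± 0.08 (adjusted p = 0.153 and 0.469).

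The pollen list was called higher by camera (median log2 fold change 0.23, adjusted p = 0.0464; adjusted p = 0.564 with an estimated correlation), with 0 of 10 tested members called, also over the list alone. VGD1 stood at 54.3 ± 9.32 FPKM in WT and 70.6 ± 5.43 in agc1-4 (log2 fold change 0.38 ± 0.12, adjusted p = 0.0777, but 0.0459 without agc1-4 replicate 2 and 0.0485 in limma on log2(FPKM + 1)). Without WT replicate 3, 5 pollen genes including VGD1 rose with a list median of 0.35, and the call of the list was lost without WT replicate 1, WT replicate 2, agc1-4 replicate 1 or agc1-4 replicate 3, without the filter on low counts and in limma with a pseudocount of 0.1 (adjusted p = 0.0586 to 0.174). Of 6 sepal and petal genes, AP3 rose 1.19-fold (adjusted p = 0.00396) and 0 fell (1 and 1 adjusted over the list alone; median -0.02, from -0.05 to 0.01 over the alternatives, camera adjusted p = 0.949); 1 fell without WT replicate 3 or without agc1-4 replicate 1. Of 10 fruit patterning genes, RPL, a replum gene, fell 1.33-fold (adjusted p = 0.000352), FUL was 1.18-fold lower (adjusted p = 0.0411) and 0 rose (1 higher and 2 lower adjusted over the list alone). The FUL call was lost in DESeq2, in limma, without WT replicate 1 or 2 and without agc1-4 replicate 2 or 3 (adjusted p = 0.0696 to 0.294). The fruit list was not called (median 0.05, from 0.02 without WT replicate 1 to 0.105 without WT replicate 2, camera adjusted p = 0.949). In it, 1 member rose without WT replicate 2, without agc1-4 replicate 1, without the filter on low counts or with the replicate block.

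**Figure D3:**
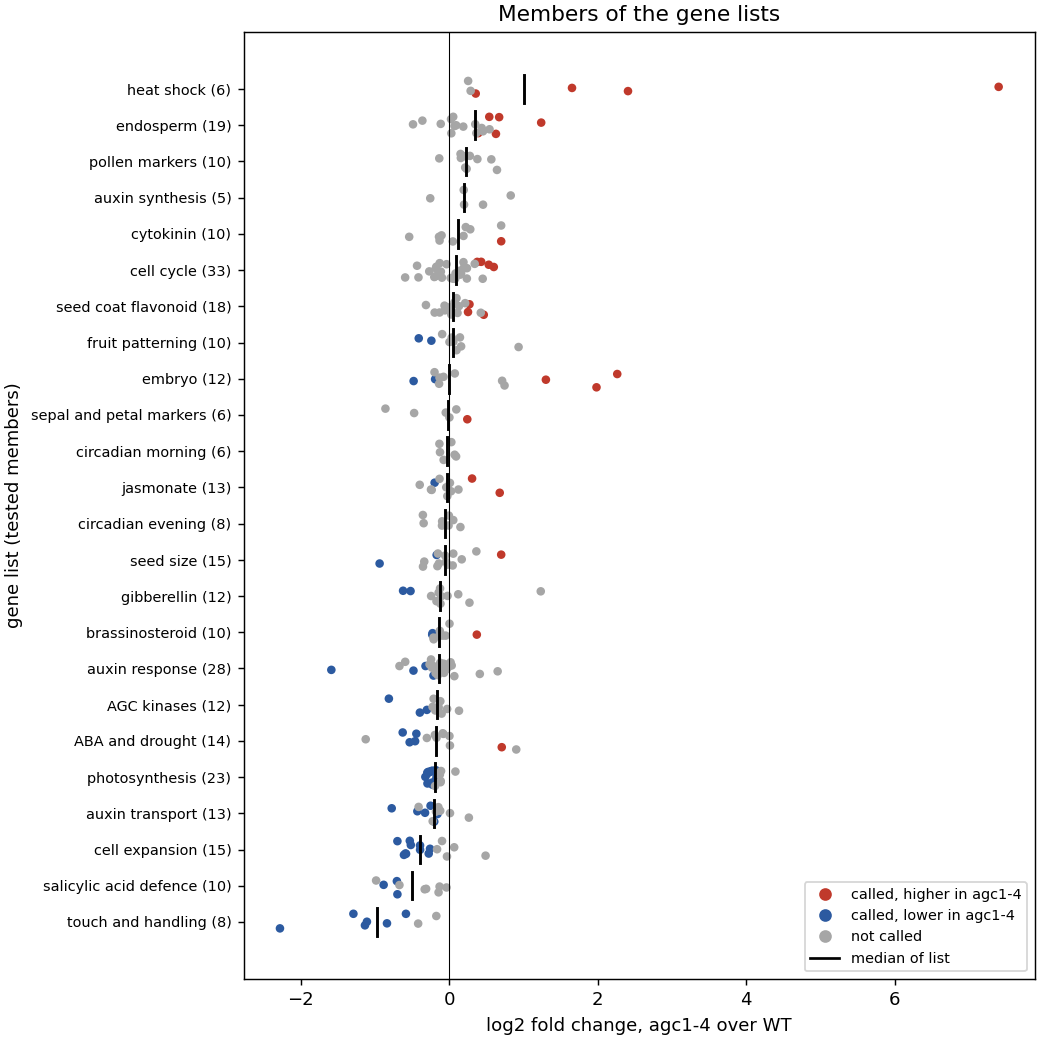
Points are the tested members of 24 gene lists (number tested in brackets), placed by log2 fold change (agc1-4 over WT, x axis), red if called higher, blue if called lower and grey if not called; black bars are list medians. The heat shock list has the highest median (1.01) and the touch and handling list the lowest (-0.97).

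In the search over GO terms, 6 of 66 terms were enriched among higher genes and 21 among lower genes. Among higher genes only 1 term was enriched with DESeq2 calls and 1 after removal of GC and length trends, and among lower genes 21 and 9. Secondary metabolic process led the higher genes, with 47 of 291 tested genes called where 19.0 were due by chance (adjusted p = 4.88e-07). Its members included the phenylpropanoid and lignin genes PAL4, IRX12 (also LAC4) and 4CL1, which rose 1.86-fold, 1.83-fold and 1.52-fold, and the glucosinolate gene GSL-OH, which rose 2.37-fold (adjusted p = 3.03e-09, 4.91e-09, 3.52e-08 and 1.2e-08). Structural molecule activity followed with 56 of 489 genes where 32.0 were due (adjusted p = 0.000399), mostly ribosomal genes such as RPS15B and AT5G24510, which rose 2.72-fold and 2.24-fold (adjusted p = 2.51e-06 and 0.00032). That term was not enriched after removal of GC and length trends, with 33 genes (adjusted p = 0.945). Among lower genes, photosynthesis led with 56 of 227 genes where 16.3 were due (adjusted p = 9.05e-15), including LHCB2.4, BCA1 and PSAH2, which fell 1.36-fold, 1.28-fold and 1.35-fold (adjusted p = 1.78e-06, 2.54e-06 and 3.03e-06). Signal transducer activity followed with 65 of 394 genes where 28.3 were due (adjusted p = 7.51e-09). Its members RPT2, a phototropism gene, and the receptor kinase genes SD16, SRF7 and RLK5 fell by 1.42-fold, 1.51-fold, 1.36-fold and 1.45-fold (adjusted p = 1.04e-05, 2.29e-05, 3.5e-05 and 0.000122).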

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

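Before the data were examined, these alternatives were fixed, except scaling by library size, removal of GC and length trends and leaving out XLOC and organellar genes, which were chosen after seeing the data. Of 1544 alternative values for the 103 named genes besides AGC1-4, 1411 kept their direction and side of the threshold, 123 lost the call, 10 gained it and 0 reversed. AGC1-4 stayed called wherever it was tested; it fell below the filters of both limma fits and of the fit without WT replicate 2. With 1 library left out, its log2 fold change ran from -3.76 to -2.26. The count of called genes was then 1688 to 2816 (852 to 1438 higher, 823 to 1378 lower, 286 to 371 with a fold of at least 2). From 7 to 12 lists were called, and fewer samples were fitted there. Without WT replicate 3, however, more genes were called than with all libraries (2816 against 2564). DESeq2 called 1590 genes, 785 higher and 805 lower. With limma on log2(FPKM + 1), 875 were lower and 145 had a fold of at least 2, and with a pseudocount of 0.1, 848 were lower; the cause was not tested. An adjusted p under 0.01 left 1428 genes and a fold of at least 2 left 305, by construction. With an estimated inter-gene correlation camera called 0 of 24 lists, 6 at an unadjusted p under 0.05, and gave the highest adjusted p over the alternatives for each of the 11. In that setting camera also rests on the few residual degrees of freedom (libraries minus genotypes), so a lost call need not come from correlated members. The estimate was below the preset 0.01 for auxin transport, endosperm and cell expansion genes (-0.077, -0.044 and -0.031). Fry, which tests a list by itself and not against other genes, called 13 lists, 10 of them among the 11. It added auxin synthesis, cell cycle and cytokinin (fry adjusted p = 0.00467, 0.029 and 0.032) and did not call pollen (fry adjusted p = 0.232). GO terms numbered 0 for calls with a fold of at least 2, where fewer genes enter, 22 for DESeq2 calls (1 higher, 21 lower) and 10 with GC and length trends removed (1 and 9), against 27 (6 and 21). Replicate numbers did not pair the libraries: correlations of deviations were -0.03, 0.01 and 0.03, and not every library correlated best with its own number. With the replicate block, 2643 genes and 11 lists were called, and 3 pollen genes where 0 were without it. The DESeq2 fit was not run for the lists, which camera tests. Depth limited low genes: 3 counts were 0.254 to 0.376 CPM.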

Other observations

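The gene families, the genes named from them and the pathways here were chosen after the results were seen, as were the tests of seed tissue share, harvest hour and batch. Genes of small secreted defensin-like proteins were higher in agc1-4: 46 of 99 tested rose and 2 fell (median log2 fold change 0.51; camera adjusted p = 8.9e-24; adjusted p = 0.108 with an estimated correlation). LCR46 rose from 9.12 ± 2.81 to 35.5 ± 4.19 FPKM (SD, n = 3; edgeR adjusted p = 1.47e-08), LCR73 from 21.8 ± 4.56 to 62.7 ± 8.25 (adjusted p = 1.49e-08) and AT5G55132 from 637 ± 19.2 to 910 ± 24.1 (adjusted p = 4.58e-08). After removal of GC and length trends 32 rose and 8 fell. Genes of secondary wall and lignin formation rose too, 13 of 20 with 0 fallen (median 0.43; camera adjusted p = 1.34e-17; adjusted p = 0.066 with an estimated correlation), and 15 after that removal. IRX10 and IRX15, genes of xylan synthesis, rose from 44.7 ± 3.1 to 71.7 ± 5.39 and from 16.1 ± 0.395 to 30.9 ± 2.15 FPKM, and the laccase gene LAC11 from 3.25 ± 0.415 to 6.77 ± 0.148 (adjusted p = 2.6e-08, 1.01e-08 and 1.38e-05). Phenylpropanoid biosynthesis was among 4 of 111 KEGG pathways enriched among higher genes, with 16 of 78 genes (hypergeometric adjusted p = 0.00791).

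Genes whose description holds the word receptor-like, which include kinases and others such as TIR (AT1G72930), were lower: 46 of 185 tested fell and 2 rose (median log2 fold change -0.15; camera adjusted p = 4.01e-09; with an estimated correlation, adjusted p = 0.0386 over the 6 families chosen after the results and 0.0644 over these and the 24 lists together), and 41 fell and 2 rose after removal of GC and length trends. AT1G35710 fell from 18.9 ± 1.65 to 9.95 ± 0.409 FPKM and PXC1, a vascular kinase gene, from 27.2 ± 0.904 to 17.3 ± 0.678 (adjusted p = 8.03e-10 and 2.18e-07). Of 41 WRKY genes, 7 fell and 0 rose (camera adjusted p = 0.000628; adjusted p = 0.143 with an estimated correlation). They include WRKY33, WRKY40 and WRKY53 of the touch list and WRKY54 and WRKY70 of the salicylic acid list, so this family is not separate evidence. Genes of cutin, suberin and wax synthesis stood among the 13 KEGG pathways enriched among lower genes, with 8 of 16 genes (adjusted p = 0.000101). Core histones and cytosolic ribosomal proteins rose by small amounts, 16 of 35 and 40 of 199 with 0 fallen, but 8 and 16 rose after removal of GC and length trends (camera adjusted p = 4.01e-09 and 8.68e-11 without that removal; adjusted p = 0.147 and 0.213 with an estimated correlation).

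DIR1 lost all of its counts in agc1-4. Reads assigned to its neighbouring relative AT5G48490 in place of DIR1 are argued against, since DIR1 lost 22.2 CPM while AT5G48490 changed by -1.54. A deletion reaching the next genes is argued against by their log2 fold changes, 0.04 ± 0.07 (SE) for AT5G48480 and -0.33 ± 0.19 for AT5G48490. A deletion or sequence difference within DIR1 in the mutant line, and an effect of the agc1-4 genotype on the gene, may each account for the loss and stay untested.

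Endosperm genes were higher while photosynthesis and cell expansion genes were lower, list calls that were lost with an estimated correlation (adjusted p = 0.103, 0.29 and 0.0512). The estimates were -0.044, 0.379 and -0.031, so those for endosperm and cell expansion genes were not above the preset 0.01. The loss of the endosperm and cell expansion calls therefore cannot be put down to correlated members. After removal of GC and length trends, 96.7% of the called members of these lists (29 of 30) stayed called in the same direction. They were picked as called before that removal. Over all tested members, the median went from 0.353 to 0.239 for endosperm genes. It went from -0.189 to -0.219 for photosynthesis genes and from -0.39 to -0.397 for cell expansion genes. These medians argue against GC or length bias as the whole cause, though the endosperm rise was smaller after the removal. A larger share of seed tissue in agc1-4 siliques may account for the pattern, and it would raise seed coat genes with endosperm genes. The mean log2 fold changes were 0.27 for endosperm and 0.08 for seed coat flavonoid genes. Shuffling genes between these lists gave a permutation p of 0.0724 for the difference. Libraries were not shuffled, so that p does not measure the spread between libraries. It also treats genes as independent, while the estimated correlation was 0.296 for seed coat genes (-0.044 for endosperm genes). That test therefore leaves a larger share of seed tissue open. The design leaves altered growth in the mutant open too, since tissue makeup and genotype go together.

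Touch and salicylic acid genes were lower while heat shock genes were higher, list calls that were lost with an estimated correlation (adjusted p = 0.103, 0.188 and 0.0568). In each of the 6 fits without 1 library, 100% of the 13 called members kept their direction and at least 50% of their log2 fold change. Of these members, 11 or 12 stayed called. They were picked as called with all 6 libraries, so they cannot exclude a library standing apart. Over all tested members, medians without 1 library ran from -1.091 to -0.783 for touch genes. They ran from -0.647 to -0.405 for salicylic acid genes and from 0.866 to 1.163 for heat shock genes. Harvest at another hour of the day found no support, as 0 of 14 clock genes was called in edgeR and 12 of them stayed at or below 0.555 in size plus 2 SE (CCA1 0.03 ± 0.06, LHY -0.07 ± 0.07, GI -0.01 ± 0.06, SE). It stays open, since the bound of 1 set for all 14 was passed by 1 weakly measured gene, ELF4 (-0.34 ± 0.44, size plus 2 SE 1.23), and a small shift in hour has no known bound here. A growth or harvest batch that coincides with genotype cannot be told apart from an effect of the mutation on stress responses, as the labels name 0 batches.

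Of the called genes with a fold of at least 2, 4 lay within 100 tested genes on either side of AGC1-4, where the median over windows of that size was 3 and a share of 0.408 of windows held as many. That count depends on the window: AT5G38195 lay at its edge, with AT5G38160, AT5G38170 and AT5G38180 just beyond. With 50, 110, 150 and 200 genes on either side, widths chosen after the first result, 2, 7, 9 and 9 lay in the window and the shares were 0.473, 0.0554, 0.0397 and 0.203, so a sequence difference linked to the mutated locus is neither shown nor excluded. The 10 splits of the 6 libraries into groups of 3 are too few for a share under 0.05: 1 split, the real one, gave as many as 2564 genes, and the highest of the others gave 1. For called lists, 1 split, the real one, gave as many as 11, and the highest of the others gave 5. The other splits each mix the genotypes, so any genotype difference enlarges the spread within their groups and holds down their gene calls. They are therefore no measure of chance.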
